A study of Homo sapiens with 4 samples.

How the data were processed

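Small RNA was profiled in MCF-7, an established oestrogen receptor-positive human breast cancer cell line, on 4 single-colour Cy3 microarrays. Each array held RNA of cells treated for 18 h with vehicle, DDT, bisphenol A (BPA) or 17β-oestradiol (E2), with 1 array per treatment. Per the labels' protocols, the cells were kept before dosing in phenol red-free medium with charcoal-stripped serum, which lowers the oestrogen in the medium. The doses, the vehicle and the isomer of DDT are not given in the sources used here. Per the labels' protocols, the small RNA fraction was isolated by size, tailed with poly(A) and ligated to a tag that was stained with Cy3, and a service company, LC Sciences, ran the arrays.

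The deposited scanner files hold 1 intensity per spot on a linear scale, with no background column and no flags. The files carry no record of background subtraction or scaling by the authors, and their empty spots read 184 to 244 units, so the intensities were treated as uncorrected. Each array had 3968 spots, among them 4 repeat spots for each of 856 human miRNA probes, 252 empty spots and the spots of 49 control probe names. A second deposited table holds the authors' processed intensity values for 905 probe names, of which 856 are the miRNA probes. Set against the spot intensities above the empty spots, these values follow a linear scale, with slopes of 0.891 to 1.28 between log10 values over the probes that pass the stricter filter described below. The column medians of that table were 21.1 for vehicle, 20.2 for DDT, 19.4 for BPA and 21.3 for E2. How the authors normalized that table, and whether it was centred, is not given in the sources used here, and it entered only as an alternative.

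Spot intensities were corrected for background with the normexp method of limma 3.58.1 in R 4.3.3, fitted on all spots of an array, with an offset of 50. Control spots were then left out, the miRNA spots of the 4 arrays were quantile normalized, and log2 values of the 4 repeat spots of a probe were averaged. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A probe was called detected where its median spot exceeded the median of the empty spots by more than 3 SD of the empty spots. Most probes that met this criterion read close to the typical miRNA probe, so a stricter filter was added after the data were seen. It asks that a probe's median spot exceed the median of the 856 miRNA probes by 3 scaled median absolute deviations.

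The precision is limited by the number of arrays. With no replicate arrays there is no test across samples, no p-value and no replicate check of any difference. The standard error given with each log2 difference combines the SD of the 4 repeat spots on each of the 2 arrays, and it covers error within a hybridisation only. Differences of at least 2-fold were counted over miRNAs detected on both arrays. A miRNA detected on only 1 of 2 arrays was given a bound, the brighter level against the higher of the lowest level among detected probes and the probe's own level on the other array.

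The procedure was tested on 4 simulated arrays whose miRNA signal came from the vehicle array, with all 856 probes in the fit. Their empty spots took the level and SD of each real array. On the simulated DDT array, 8 probes past the stricter filter were changed per size of effect. True log2 differences of 2 and -2 came back with medians of 1.28 and -1.36, and true differences of 1 and -1 with medians of 0.59 and -0.82. The sign was right in 100% of these probes, and 0 of 350 unchanged probes passed 2-fold. Beyond spot noise and an array-wide scale, unchanged probes were given no differences between arrays. That count therefore says nothing about 2-fold differences between real arrays. In these simulations true differences thus came back smaller, and which step shrank them was not tested. A normalized difference can also exceed the unnormalized one, as for miR-92a on DDT against vehicle, at -1.42 with normalization and 0.02 without.

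The named miRNAs follow a rule fixed before the data were examined. It takes the 10 highest and 10 lowest differences of each treated array against vehicle among those larger than 2 standard errors, the 5 highest and 5 lowest between treated arrays, up to 5 bounds of at least 2-fold per direction, the 2 to 4 members with the largest difference in each fixed list, and always miR-21, let-7a, miR-206, miR-221, miR-222, miR-18a, miR-210 and miR-122. The 22 lists, also fixed before, cover miRNA families and clusters, miRNAs tied to the oestrogen receptor, hypoxia and stress, fragments of other small RNAs, star strands, and markers of other cell types. The median of each list with at least 3 detected members was placed among 10000 random lists of the same size matched on signal in 5 bins, as a description of these arrays. Correlations between the 3 responses were set beside 1000 simulations with no treatment effect and the same shared vehicle array, and intervals come from 1000 bootstrap resamples of miRNAs.

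Probe names were matched to the gene table of assembly GRCh38.p14. Of 856 names, 838 matched a gene, 834 of them annotated as a miRNA gene, and 18 had no match. The files name no genome build, so no coordinates are given, and the table was used only for names and for genes that span or lie within 10 kb of a miRNA gene. Alternatives listed before the data were examined were plain background subtraction, no background correction, an offset of 16, scaling to the median of the miRNAs detected on all 4 arrays, cyclic loess, no normalization, detection on all 4 arrays, no detection filter, the median of repeat spots, 2 of the 4 repeat spots, the authors' processed values with a pseudocount of 50, and a threshold of 1.5-fold. Alternatives added after seeing the data were the stricter filter, scaling to the 6 probes for 5S RNA, scaling to 11 calibration spikes, and removal of a linear trend with the GC content of the target. The trend was fitted on miRNAs past the stricter filter on both arrays and subtracted from all miRNAs compared, dim ones included.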

Results

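The data comprised 4 arrays of small RNA from MCF-7 breast cancer cells, with 1 array each for vehicle, the pesticide DDT, the plasticiser BPA and the natural oestrogen E2, all after 18 h. The series states that there were no biological or technical repeats, so no difference between arrays could be set against a spread between replicates. Errors below are standard errors of 4 repeat spots per array unless stated otherwise. Of 856 human miRNA probes, 478 were detected on the vehicle array, 678 on the DDT array, 119 on the BPA array and 476 on the E2 array. The stricter filter was passed by 111, 93, 91 and 72 probes, respectively. The low count of detected probes on the BPA array went with noisier empty spots, whose SD was 19.7 units against 9.03 on vehicle, 9.43 on DDT and 12.2 on E2. Over the 57 miRNAs that passed the stricter filter on all 4 arrays, the median intensity above the empty spots was 666 units for vehicle, 1020 for DDT, 249 for BPA and 277 for E2.

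The control probes also separated the BPA and E2 arrays from the vehicle and DDT arrays. Probes with mismatches to a control RNA read a smaller share of their perfect-match partner on BPA and E2 than on both other arrays for 7 of the 7 mismatch probes that passed the stricter filter on vehicle. Of these 7, 4 were close to background on the BPA and E2 arrays, and not detected on BPA, so their ratios there carry little weight. The 3 that passed the stricter filter on all 4 arrays, PUC2MM, Ctr09-3M05 and Ctr09-3M10, all had this order, and the last 2 share a partner. The probe Ctr09-3M10 read 3.02% of its partner on vehicle and 2.21% on DDT, against 0.448% on BPA and 0.178% on E2. Of the 20 mismatch probes near background, 3 had this order. The median SD of repeat spots, in log2 units over probes past the stricter filter, was 0.10 for vehicle, 0.08 for DDT, 0.28 for BPA and 0.18 for E2. The labels give no batch, slide or date, and each array held 1 treatment, so a batch and a treatment cannot be told apart.

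**Figure D1:**
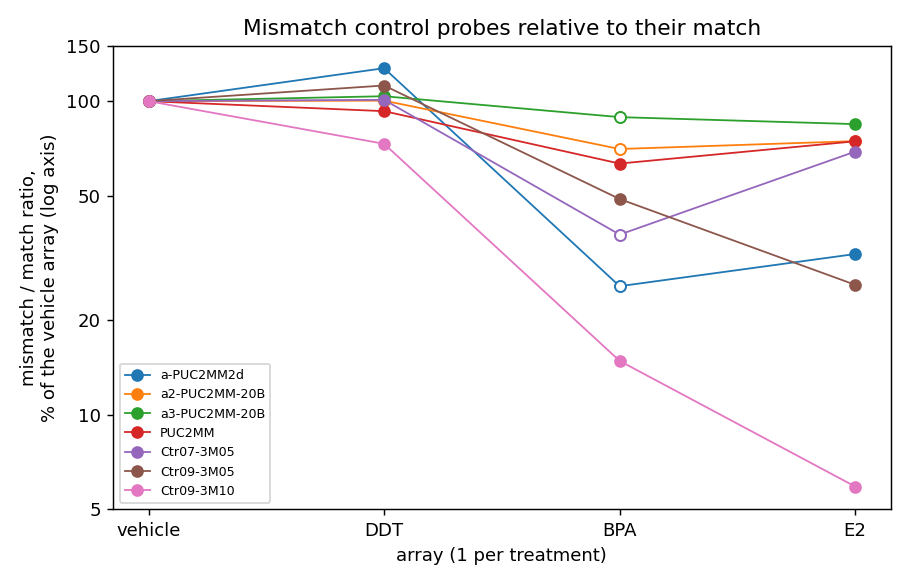
Signal of 7 mismatch control probes as a percentage of their perfect-match partner, relative to the vehicle array (log axis), on each of the 4 arrays. Each line is 1 probe, open points mark the 4 probes not detected on BPA, and all 7 lie lower on BPA and E2 than on vehicle and DDT, although these 4 were close to background there.

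The DDT and vehicle arrays were compared to find which miRNAs differed after exposure to DDT. miR-1246, whose sequence is also part of U2 small nuclear RNA, was 7.02-fold higher on the DDT array (log2 difference 2.81 ± 0.14), and miR-720, a tRNA fragment, was 4.02-fold higher (2.01 ± 0.09). The GC-rich miR-638, encoded within DNM2, was 2.98-fold higher. miR-15b, which with miR-16 represses BCL2, was 3.84-fold lower (-1.94 ± 0.07), and miR-181a was 2.25-fold lower (-1.17 ± 0.06). miR-21, an abundant miRNA in many tumours that is encoded within the span of VMP1, was 1.88-fold lower (-0.91 ± 0.10), and it was higher by 0.42 when arrays were scaled to calibration spikes.

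Of 459 miRNAs detected on both arrays, 6 were at least 2-fold higher on DDT and 3 at least 2-fold lower. The higher ones were miR-1246, miR-720, miR-638, miR-149*, miR-1915 and miR-1469, and the next by size were miR-575 at 0.98, miR-663 at 0.95, miR-1280 at 0.60 and miR-574-5p at 0.58. In spot intensity above the empty spots, miR-1246 read 256 ± 35.9 (SD of 4 spots) on vehicle and 4656 ± 450 (SD of 4 spots) on DDT, a ratio of 18.2. The corresponding ratio for miR-720 was 10.2. The lower ones were miR-15b, miR-92a and miR-181a, followed by miR-27b at -0.99, miR-92b at -0.80, miR-26a at -0.75, miR-122 at -0.74, miR-16 at -0.70 and miR-107 at -0.60. miR-575 missed the stricter filter on vehicle and miR-122 on DDT. The value for miR-92a, -1.42 ± 0.26, came with nearly equal unnormalized intensities, 4006 above the empty spots on vehicle and 4063 on DDT, and without normalization its difference was 0.02. Scaled to calibration spikes, miR-16, miR-26a, miR-92b and miR-107 were higher on DDT by 0.40, 0.55, 0.24 and 0.44.

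Among the fixed lists, fragments of other small RNAs stood highest on the DDT array. All 8 detected members were above 0, 6 of them by more than 2 standard errors, and the median of 0.53 lay at the 99.97th percentile of random lists. With the GC trend removed the median was 0.28 (percentile 97.0), inside the middle 95% of random lists, or 0.22 (percentile 96.9) when the fragments entered the fit of the trend. After miR-1246 and miR-720, the largest were miR-1280 at 0.60 and miR-1274b at 0.54. The 6 control probes for 5S ribosomal RNA, which were not part of the normalization, were 1.69-fold higher on the DDT array in intensity above the empty spots, against 1.29-fold for the median miRNA past the stricter filter on both arrays. This excess of 5S RNA over miRNA, 0.39 in log2 units on DDT, was larger on BPA and E2, at 0.75 and 0.55, where the fragment list had medians of 0.03 and 0.04. The differences of single miRNAs also followed the GC content of the target, with a Spearman rho of 0.35 (95% bootstrap interval 0.12 to 0.55) across 85 miRNAs.

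With quantile normalization, miRNA families on the DDT array were mostly at or below vehicle, but many of these medians turned positive with spike scaling. Spike scaling moved the whole comparison, with the median miRNA at 0.83 past the stricter filter and 0.51 over all detected. Without normalization these medians were 0.27 and 0.12. A positive list median in those settings, here and in the lists below, therefore does not place a list above other miRNAs. All 5 members of the miR-23/27/24 clusters were lower by more than 2 standard errors, led by miR-27b at -0.99 and miR-23b at -0.56, and the list median was -0.47 (percentile 1.96), although it was 0.05 without normalization and 0.70 with spike scaling. All 5 members of the miR-30 family were lower, among them miR-30d at -0.59 and miR-30b at -0.45, with a median of -0.39 (percentile 0.46) that became 0.08 with spike scaling and -0.21 (percentile 11.2) with the GC trend removed. In miR-17-92 and its paralogous clusters 9 of 11 members were below 0, with miR-92a, miR-106b at -0.41 and miR-106a at -0.29 the lowest. The median of that list, -0.18 (percentile 1.59), became 0.02 without normalization and 0.46 with spike scaling. The let-7 family, which represses RAS and HMGA2, had a median of 0.08 (percentile 83.3), with let-7e at 0.42, let-7c at 0.36 and let-7g at -0.30. With the GC trend removed its median was 0.36 (percentile 99.7 of random lists, which were not matched on GC content). The miR-200 family was at -0.14 (percentile 9.98), led by miR-200b and miR-200a at -0.26 each, and at 0.04 without normalization, 0.45 with spike scaling and 0.14 once the GC trend was removed. The miR-181 family was at -0.21 (percentile 9.75), or 0.32 with spike scaling. In the miR-26 family, which has 2 members, miR-26a was lower and miR-26b was at 0.18.

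Among lists tied to the oestrogen receptor, miRNAs reported as oestrogen-responsive in MCF-7 had a median of -0.18 (percentile 0.25), with 14 of 21 members below 0. Members went both ways, with miR-638 at 1.58, miR-663 at 0.95, miR-181a at -1.17 and miR-27b at -0.99. The median was 0.06 without normalization, 0.54 with spike scaling and 0.07 once the GC trend was removed. miRNAs known to target ESR1, the oestrogen receptor gene, had a median of -0.01 (percentile 67.2), with miR-222 at 0.21 and miR-206 at 0.15, and were at 0.14 without normalization, 0.52 with spike scaling and 0.18 once the GC trend was removed. Of the 9 detected members of the ESR1 list, 2 passed the stricter filter on both arrays. The list of miRNAs higher in oestrogen receptor-positive luminal tumours had a median of -0.14 (percentile 4.77), led by miR-26a at -0.75 and miR-342-3p at -0.49, and was at 0.07 without normalization and 0.49 with spike scaling. The p53-linked miR-34 family with its relatives lay at 0.02 (percentile 67.6), or -0.25 with 5S scaling and -0.19 with scaling to the median of miRNAs detected on all arrays. On DDT against vehicle 5 of 19 list medians lay outside the middle 95% of random lists, those of the fragments, miR-30, miR-23/27/24, miR-17-92 and the oestrogen-responsive list. With the GC trend removed all 5 lay inside, among them miR-23/27/24 at -0.46 (percentile 3.15), and let-7 at 0.36 (percentile 99.7) lay outside.

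The counts for DDT depend on the scaling. They were 7 higher and 7 lower with cyclic loess, 14 and 2 without normalization, 7 and 6 scaled to 5S RNA, 41 and 0 scaled to calibration spikes, and 2 and 5 once the GC trend was removed.

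**Figure D2:**
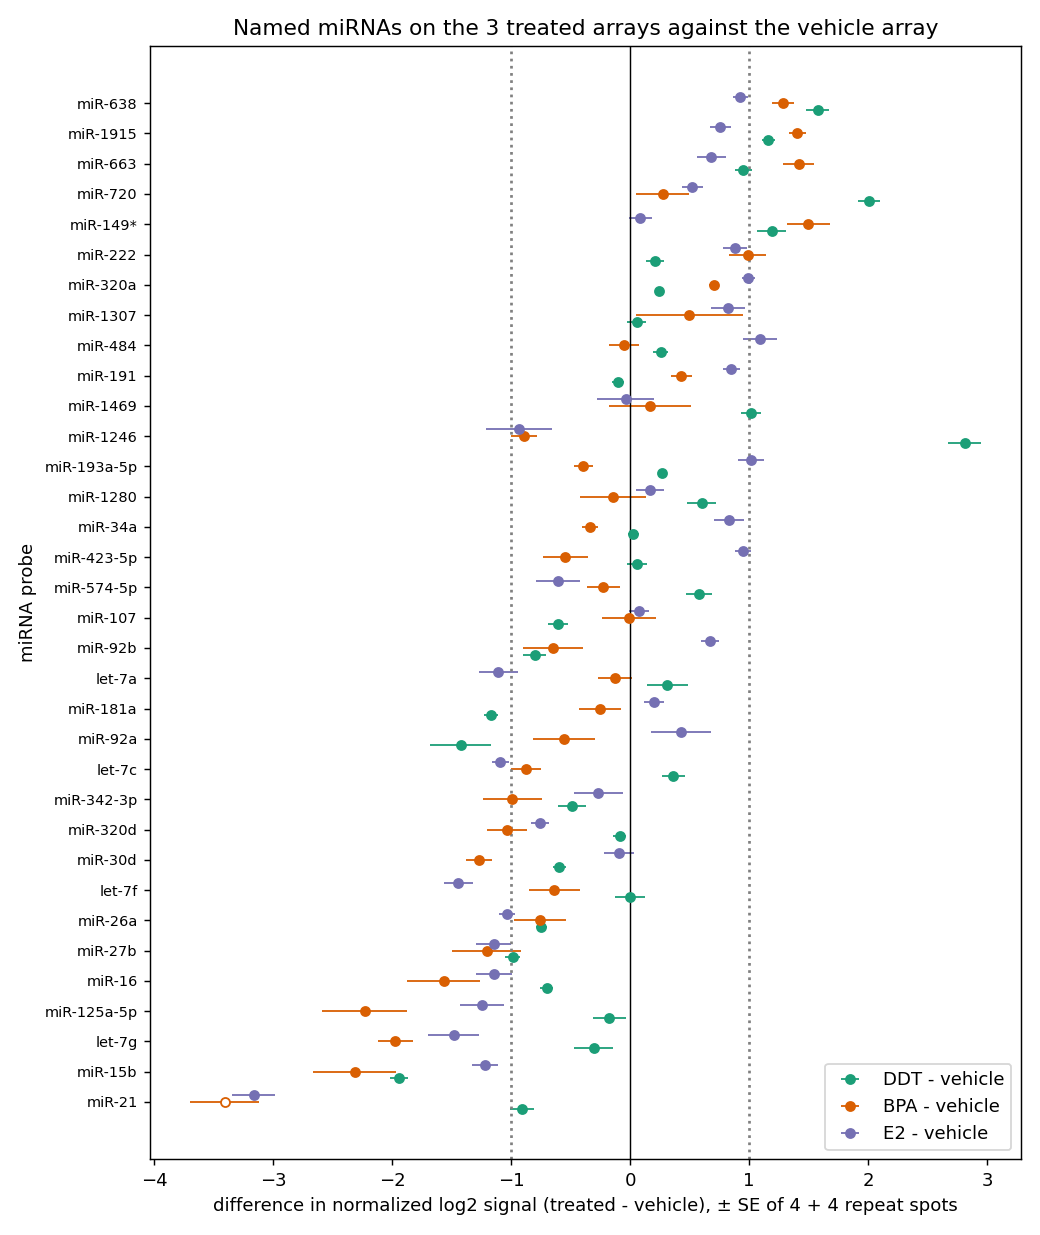
Difference in normalized log2 signal between each treated array and the vehicle array for the named miRNAs that passed the stricter filter on both arrays in at least 1 comparison. Points are means of 4 repeat spots per array, bars are standard errors of repeat spots, dotted lines mark 2-fold, and the open point is miR-21 on BPA, where it was not detected. miR-1246 at 2.81 on DDT and miR-21 at -3.16 on E2 lie farthest from 0 among detected values.

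The BPA and vehicle arrays were compared to find miRNAs that differed after BPA. miR-21 was detected on vehicle at a log2 level of 10.55 and was not detected on BPA, where it was at least 10.6-fold lower. miR-15b was 4.98-fold lower on BPA (-2.32 ± 0.35), and miR-16, 1 of whose 2 genes lies beside that of miR-15b within SMC4, was 2.96-fold lower (-1.57 ± 0.31). miR-125a-5p, which targets ERBB2, was 4.70-fold lower (-2.23 ± 0.36), and let-7g was 3.92-fold lower (-1.97 ± 0.15). miR-149*, miR-663, miR-1915 and miR-638 were 2.44- to 2.83-fold higher, with standard errors of 0.07 to 0.18, but none of them stayed 2-fold higher with the GC trend removed.

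Of 104 miRNAs detected on both arrays, 6 were at least 2-fold higher on BPA and 8 at least 2-fold lower. miR-30d at -1.27, miR-27b at -1.21, miR-106b at -1.06, which missed the stricter filter on BPA, and miR-320d at -1.04 completed the lower group, and miR-342-3p at -0.99 and miR-1246 at -0.89 came next. The difference of miR-1246 was 0.09 with cyclic loess. miR-222, which represses the cell cycle inhibitor CDKN1B, was higher by 0.99 ± 0.16. The other higher miRNAs were miR-130a* (1.17 ± 0.46), miR-129-5p (1.02 ± 0.34), miR-195* (0.96 ± 0.31), miR-106b* (0.94 ± 0.27) and miR-18b* (0.82 ± 0.27), all of which missed the stricter filter on vehicle. miR-937, encoded within SCRIB, was detected on BPA and not on vehicle and was at least 4.06-fold higher, while miR-200b was at least 2.84-fold lower. Without normalization miR-663, miR-1915 and miR-638 were lower on BPA, by -0.16, -0.13 and -0.26, and with spike scaling by -0.14, -0.11 and -0.23.

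By group, 8 let-7 members were detected on both arrays, 4 above and 4 below 0, with a median of 0.00 (percentile 50.6). Among them, let-7c was at -0.87 while let-7b was at 0.41. With the GC trend removed the let-7 median was 0.645 (percentile 99.3), outside the range of random lists, -0.357 to 0.615, which were not matched on GC content. The oestrogen-responsive list had 8 of 11 detected members below 0 and a median of -0.60 (percentile 4.04), which became 0.09 with the GC trend removed, and miR-21 stands outside that median because it was not detected on BPA. Of the miR-15/16 family, miR-15b and miR-16 were the 2 detected members, and both were past 2-fold. The miR-23/27/24 clusters had a median of -0.15, inside the range of random lists, with miR-27b at -1.21, miR-27a at -0.20 and miR-24 at 0.17, and were at 0.20 with the GC trend removed. miR-17-92 and its paralogous clusters had a median of -0.58 (percentile 14.0), with miR-106b at -1.06, miR-20a at -0.64 and miR-93 at 0.53. The list of miR-99/100, miR-125 and miR-10 held miR-125a-5p at -2.23 and miR-99b at 0.40, and its median of 0.36 (percentile 71.7) turned negative under 4 scalings, among them -1.16 without normalization. Of 15 star strands detected on both arrays, 15 were above 0, with a median of 0.45 (percentile 92.3), on an array whose detection limit lay higher than that of vehicle. Fragments of other small RNAs had a median of 0.03 (percentile 49.0), which was -0.73 without normalization. In that setting the median miRNA past the stricter filter was itself at -1.07 on BPA.

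Differences between BPA and vehicle followed the GC content of the target, with rho = 0.47 (0.24 to 0.64) across 62 miRNAs. The median was -0.13 for 13 miRNAs with a GC content under 45% and 0.22 for 18 with one over 55%. The counts were 0 higher and 36 lower without normalization, 0 and 32 with spike scaling, 20 and 15 with 5S scaling, 43 and 10 with scaling to the median of miRNAs detected on all arrays, and 8 and 4 with the GC trend removed. In that last setting 6 of the miRNAs counted had not passed 2-fold before.

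The E2 and vehicle arrays were compared to find miRNAs that differed after the natural oestrogen. miR-21 was 8.96-fold lower on E2 (-3.16 ± 0.18), with intensities above the empty spots of 70.6 ± 13.0 (SD of 4 spots) on E2 and 2148 ± 120 (SD of 4 spots) on vehicle. Of 9 let-7 members 4 were at least 2-fold lower, let-7g at -1.48 ± 0.22, let-7f at -1.44 ± 0.12, let-7a at -1.11 ± 0.16 and let-7c at -1.09 ± 0.07, and of these let-7g alone stayed 2-fold lower with the GC trend removed. miR-200b, which represses the mesenchymal regulators ZEB1 and ZEB2, was lower by a log2 difference of -1.51 ± 0.10, although it missed the stricter filter on E2, so the size of its difference is uncertain. miR-484 was 2.13-fold higher (1.09 ± 0.14) and miR-193a-5p was 2.02-fold higher (1.01 ± 0.11). Neither was 2-fold higher without normalization, without background correction, with cyclic loess, with 5S or spike scaling, or with the GC trend removed.

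Of 320 miRNAs detected on both arrays, 2 were at least 2-fold higher on E2 and 11 at least 2-fold lower. miR-125a-5p at -1.25, miR-15b at -1.22, miR-27b at -1.14, miR-16 at -1.14 and miR-26a at -1.04 completed the lower group with the 6 miRNAs above. Next among the higher ones were miR-320a at 0.99, miR-423-5p at 0.95, miR-638 at 0.93, miR-222 at 0.88, miR-191 at 0.85, miR-34a at 0.83 and miR-1307 at 0.82. miR-1260, which missed the stricter filter on vehicle, had a difference of 0.89 with a standard error of 0.40. Without normalization miR-320a, miR-423-5p, miR-638, miR-222, miR-191 and miR-34a were below vehicle, at -0.41, -0.12, -0.70, -0.03, -0.89 and -0.04. miR-320a, miR-638 and miR-191 were also lower with spike scaling, at -0.06, -0.34 and -0.53, and miR-638 and miR-191 with 5S scaling, at -0.25 and -0.44.

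By group, 8 of 9 let-7 members were below 0 on E2 and 4 were past 2-fold, while let-7b was at 0.52, 4 members lay between -0.06 and -0.01, and the list median was -0.06 (percentile 14.9), or 0.28 with the GC trend removed. The miR-15/16 family had 3 of 3 detected members lower and a median of -1.14 (percentile 1.41), and of the 6 lists outside the middle 95% of random lists on E2 it was the 1 that stayed outside with the GC trend removed, at -0.89 (percentile 1.33). The miR-30 family had 4 of 4 detected members below 0, with miR-30c at -0.81 and miR-30b at -0.72, and a median of -0.56 (percentile 1.55), or -0.29 (percentile 35.5) with the GC trend removed. Only 1 of them, miR-30d at -0.09, passed the stricter filter on both arrays. The miR-200 family had a median of -0.35 (percentile 5.30), with miR-200a at -0.52 and miR-200c at 0.43, and it was at 0.21 with scaling to the median of miRNAs detected on all arrays. With the GC trend removed it was at -0.01 (percentile 40.1). Only miR-200c, which was higher, passed the stricter filter on both arrays. The miR-181 family was at -0.34 (percentile 12.9), with miR-181c at -0.61 and miR-181a at 0.20, and the miR-29 family at 0.00 (percentile 37.6), with miR-29a at -0.45. With the GC trend removed they were at -0.13 (percentile 49.7) and 0.50 (percentile 92.0). miR-181c and all detected miR-29 members missed the stricter filter.

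The list of oestrogen-responsive miRNAs had 13 of 19 members below 0 on E2, 6 of them past 2-fold, and a median of -0.20 (percentile 0.81), or -0.18 (percentile 4.39), inside the middle 95% of random lists, with the GC trend removed. Its lowest members were miR-21, miR-200b, let-7f and miR-27b, and its highest was miR-638. miRNAs higher in luminal tumours had a median of -0.27 (percentile 0.585), with miR-26a at -1.04 and miR-203 at -0.86, and were at 0.54 with scaling to the median of miRNAs detected on all arrays and at -0.28 (percentile 4.26), inside the middle 95%, with the GC trend removed. Of the 9 detected members of the luminal list, 2 passed the stricter filter on both arrays, and miR-203 was not among them. miRNAs known to target ESR1 had a median of -0.07 (percentile 15.4), in which miR-222 was at 0.88 and miR-221 at -0.66, although these 2 are encoded side by side in MIR222HG. That median was 0.34 with 5S scaling, 0.25 with spike scaling and 0.82 with scaling to the median of miRNAs detected on all arrays. In these settings the median of all miRNAs detected on both arrays was itself 0.36, 0.28 and 0.94. Past the stricter filter it was -0.34, -0.41 and 0.09. Of the 7 detected members of the ESR1 list, only miR-222 passed that filter on both arrays, and miR-221 missed it on E2. miR-17-92 and its paralogous clusters were at -0.05 (percentile 18.5), with miR-93 at 0.67 and miR-106b at -0.49, and at 0.32 with scaling to the median of miRNAs detected on all arrays and 0.17 with the GC trend removed. The hypoxia and stress list was at 0.01 (percentile 48.9) with miR-34a, which p53 induces, at 0.83 and miR-22 at -0.19. With the GC trend removed that list was at 0.395 (percentile 95.5). Of its 6 detected members, only miR-34a passed the stricter filter on both arrays. Fragments of other small RNAs were at 0.04 (percentile 66.4), with miR-1246 at -0.93 and miR-1260 at 0.89, and at -0.42 without normalization, -0.07 with spike scaling and -0.37 with the GC trend removed.

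Differences between E2 and vehicle had the highest rank correlation with the GC content of the target, with rho = 0.62 (0.45 to 0.74) across 69 miRNAs and medians of -0.49 for 17 miRNAs under 45% GC and 0.49 for 21 over 55%. The interval overlapped that of BPA against vehicle, where the fitted slope was steeper, and the difference between them was not tested. The counts were 0 higher and 5 lower once that trend was removed, 0 and 33 without normalization, 0 and 22 with spike scaling, 0 and 21 with 5S scaling, 0 and 8 with cyclic loess, and 99 and 11 with scaling to the median of miRNAs detected on all arrays. In that last setting the median over all detected miRNAs was 0.94, against 0.09 past the stricter filter, so dim miRNAs shifted as a group.

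**Figure D3:**
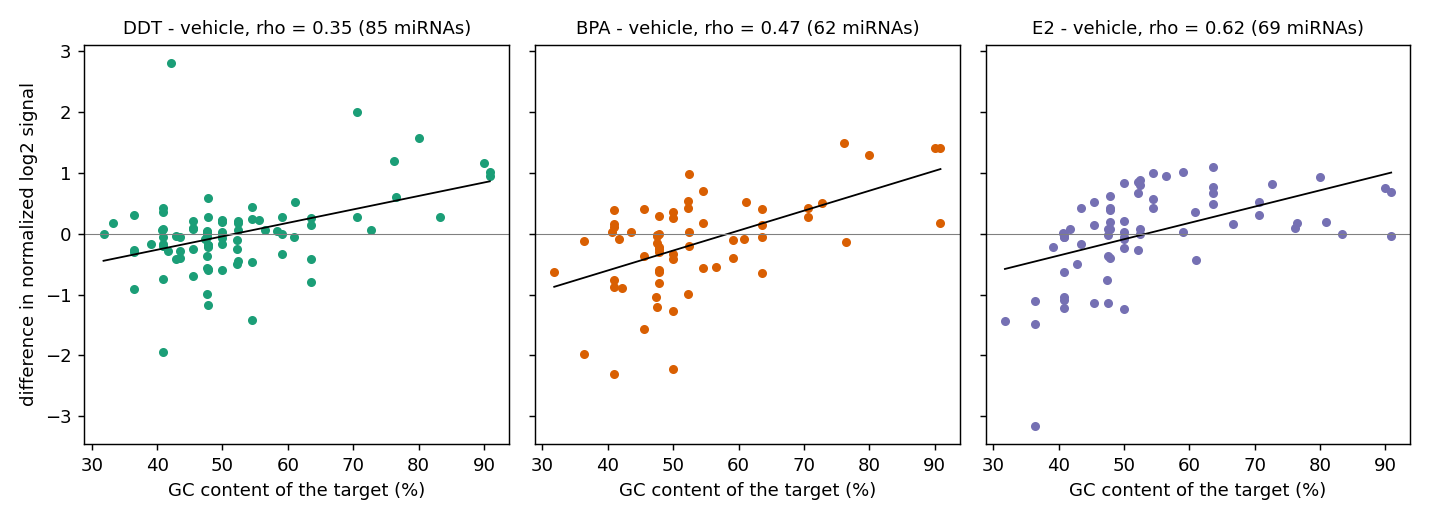
Difference in normalized log2 signal between each treated array and vehicle (vertical axis) against the GC content of the miRNA target in percent (horizontal axis). Each point is a miRNA past the stricter filter on both arrays and lines are least-squares fits, with rho rising from 0.35 for DDT to 0.47 for BPA and 0.62 for E2.

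DDT and BPA share a core of 2 phenyl rings on 1 carbon, chlorinated in DDT and hydroxylated in BPA, and their arrays were compared directly, at doses that are not given in the sources used here. miR-1246 was 13.0-fold higher on DDT than on BPA (3.70 ± 0.14), miR-125a-5p was 4.16-fold higher (2.06 ± 0.35) and miR-720 was 3.33-fold higher (1.74 ± 0.21). let-7g and let-7c were higher on DDT by 1.67 and 1.24. miR-21 was at least 5.65-fold higher on DDT, miR-200b at least 2.37-fold and miR-575 at least 2.06-fold, while miR-937 was at least 4.14-fold lower. miR-129-5p at -1.03 ± 0.34, miR-195* at -0.94 ± 0.31, miR-181a at -0.92 and miR-92a at -0.87 were lower on DDT, the last 2 of which were higher without normalization, by 0.96 and 1.44. miR-130a*, also among the 5 lowest, was just under 2-fold lower with a standard error of 0.47, and miR-129-5p, miR-130a* and miR-195* missed the stricter filter on DDT. Of 110 miRNAs detected on both, 5 were at least 2-fold higher and 1 at least 2-fold lower on DDT. Those counts were 45 and 0 without normalization, 57 and 0 with spike scaling, 12 and 42 with 5S scaling, and 15 and 48 with scaling to the median of miRNAs detected on all arrays.

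The DDT and E2 arrays set the chlorinated compound beside the steroid. miR-1246 was higher on DDT by 3.74 ± 0.29, although it missed the stricter filter on E2, so the size of its difference is uncertain. miR-21 was 4.77-fold higher (2.26 ± 0.19), and miR-720 was higher by 1.49 ± 0.05. let-7c and let-7f were higher by 1.46 and 1.44, and miR-26b was at least 2.02-fold higher. miR-92a at -1.85, miR-92b at -1.47, miR-181a at -1.37, miR-103 at -1.19 and miR-99b at -1.18 were lower on DDT with standard errors of at most 0.10, and without normalization all 5 were higher, by 0.27, 0.64, 0.47, 0.62 and 0.84. Of 407 miRNAs detected on both, 13 were at least 2-fold higher and 6 at least 2-fold lower, against 40 and 0 without normalization, 50 and 0 with spike scaling, 22 and 0 with 5S scaling and 19 and 310 with scaling to the median of miRNAs detected on all arrays. In that last setting the median over all 407 was -1.17, against 0.01 past the stricter filter, so dim miRNAs shifted as a group.

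The BPA and E2 arrays, on both of which the 3 mismatch probes above background read lower relative to their partner than on vehicle and DDT, were also compared, although the SD of their empty spots differed. miR-937 was higher on BPA by 1.86 ± 0.25, although it missed the stricter filter on E2, and miR-149* was 2.66-fold higher (1.41 ± 0.16). let-7a was 1.97-fold higher on BPA (0.98 ± 0.09), and miR-129-5p and miR-130a* were higher by 1.06 ± 0.34 and 1.03 ± 0.47 but also missed that filter on E2. miR-423-5p was 2.81-fold lower on BPA (-1.49 ± 0.18), followed by miR-193a-5p at -1.41, miR-92b at -1.32, miR-425 at -1.23 and miR-30d at -1.17. miR-106b* and miR-1228 were detected on BPA and not on E2, at least 2.23- and 2.07-fold higher. Of 98 miRNAs detected on both, 4 were at least 2-fold higher and 8 at least 2-fold lower. The GC content of the target had a rho of -0.09 (-0.38 to 0.20) with this difference, and the counts were 2 and 2 with cyclic loess, 4 and 2 with 5S scaling and 0 and 3 with spike scaling.

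Across the 90 miRNAs detected on all 4 arrays, the responses to BPA and E2 had a Pearson r of 0.58 (0.41 to 0.72), those to DDT and BPA 0.43 (0.15 to 0.69), and those to DDT and E2 0.18 (-0.10 to 0.44). Spearman's rho was 0.43, 0.45 and 0.24. In the same order r was 0.90, 0.06 and -0.06 without normalization, and 0.88, -0.06 and -0.15 with spike scaling. Scaling to the median of miRNAs detected on all arrays subtracts 1 constant per array from the unnormalized log2 values. It therefore cannot change r, which was the same as without normalization by construction. The differences had the same sign for 55.6%, 57.8% and 62.2% of the miRNAs, against 66.7% in simulations with no treatment effect. These are correlations across miRNAs, which are not independent replicates, and all 3 share the vehicle array. Between differences that share no array, r was 0.10 for BPA against vehicle and E2 against DDT. It was 0.43 for E2 against vehicle and BPA against DDT, and 0.34 for DDT against vehicle and BPA against E2. With no treatment effect, the shared vehicle array alone gave a simulated r of 0.49 (0.16 to 0.73) and a covariance of 0.233, beside observed covariances of 0.254 for BPA and E2, 0.197 for DDT and BPA and 0.067 for DDT and E2. The simulation takes the spread between arrays as noise, and with repeat-spot noise alone the simulated covariance was 0.015.

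miR-15b was at least 2-fold lower on all 3 treated arrays, but with spike scaling it was at -0.62 on DDT and with the GC trend removed at -0.89 on E2. The BPA and E2 arrays shared 5 miRNAs that were at least 2-fold lower than vehicle, miR-15b, miR-16, miR-27b, let-7g and miR-125a-5p, where independent lists would share 0.80 and simulated arrays with a shared vehicle 1.94. With the GC trend removed they shared 2, let-7g and miR-125a-5p. The DDT and BPA arrays shared 3 higher miRNAs, miR-638, miR-149* and miR-1915, where independent lists would share 0.40 and the simulation 1.92, and with the GC trend removed they shared 0. DDT and BPA shared 1 lower miRNA and DDT and E2 shared 1, miR-15b in both cases, and E2 shared 0 higher miRNAs with DDT and 0 with BPA, having 2 higher itself. The simulated counts are not matched to the number of miRNAs that passed 2-fold on each array, so no excess or lack of sharing can be read from them.

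Of the miRNAs named in advance, miR-221 had log2 levels of 7.53 on vehicle, 7.34 on DDT, 7.22 on BPA and 6.87 on E2, and miR-222 had 7.57, 7.78, 8.56 and 8.45. let-7a was at 10.79, 11.10, 10.66 and 9.68. The ESR1-targeting miR-206 and miR-18a, and the hypoxia-induced miR-210, did not pass the stricter filter on any array, with levels of 6.64 to 7.11. The liver miRNA miR-122 was at 7.43 on vehicle, at 6.69 on DDT and 6.77 on E2, and was not detected on BPA. No marker of stromal, blood, or embryonic stem and placental cells passed the stricter filter on any array. Of the liver, muscle and neuronal markers, miR-122 and miR-128 passed it on vehicle and 1 of 7 passed it on DDT. The medians of these 4 lists on DDT against vehicle were 0.04 for stromal (percentile 91.0), 0.03 for blood (87.4), 0.04 for liver, muscle and neuronal (79.2) and -0.02 for embryonic stem and placental markers (56.7). On E2 against vehicle the embryonic stem and placental list had 4 of 4 detected members above 0 and a median of 0.12 (percentile 97.7), outside the middle 95% of random lists, and was at 0.26 (percentile 88.4), inside it, with the GC trend removed. On DDT with 5S scaling the first 3 were -0.19, -0.19 and -0.26, and with spike scaling the last was 0.49. Star strands had a median of -0.02 (percentile 58.2) over 95 detected on DDT and vehicle, 0.49 with spike scaling, and 0.03 (percentile 98.9) over 60 detected on E2 and vehicle, where it was at 0.12 (percentile 54.4) with the GC trend removed.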

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

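The tests on mismatch control probes and on 5S RNA, and the removal of the GC trend, were chosen only after the results were seen. The control probes for 5S ribosomal RNA lie outside the miRNA probes used in the comparisons. They drew attention because they read 1.69-fold higher on the DDT array than on the vehicle array, more than the 1.29-fold of the median miRNA. Relative to the median miRNA they were also higher on BPA and E2, by 0.75 and 0.55 in log2 units against 0.39 on DDT, so the excess was not particular to DDT.

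On the BPA and E2 arrays, miRNAs with a low GC content were lower and those with a high GC content higher than on vehicle. With less labelled miRNA, and dim miRNAs lost in the background, GC content should be unrelated to the difference at a fixed vehicle level. At a fixed level the rank correlation stayed above 0, with the lower end of its interval at 0.256 or more on both arrays. This covers 62 miRNAs on BPA and 69 on E2 past the stricter filter, among which vehicle level alone did not account for the trend. miRNAs lost in the background were not among them, so their loss was not tested. More stringent hybridisation or washing on the BPA and E2 arrays may explain part of the trend, since 7 of 7 mismatch probes above background on vehicle read lower relative to their match on both arrays, although 4 of them were near background there and the weight rests on the 3 others. A trend was also present on DDT against vehicle (rho 0.35, 0.12 to 0.55), which stringency on BPA and E2 alone would not give. Stringency also predicts a trend against the DDT array. There rho was -0.22 (-0.476 to 0.055) for DDT against E2 and -0.21 (-0.442 to 0.034) for DDT against BPA, with 0 inside both intervals. The trends against vehicle all share the vehicle array. A response of the cells to BPA or E2 cannot be told apart from stringency with 1 array per treatment, and of 27 2-fold differences on these 2 arrays 10 stayed 2-fold once the trend was removed, while 7 others passed 2-fold, making 17. Among the 7, miR-148b*, miR-195* and miR-223 on BPA missed the stricter filter, so they lay outside the fit of the trend and may be products of its removal. miR-15b, miR-16, let-7g and miR-125a-5p on BPA, and miR-21, miR-200b, let-7g and miR-125a-5p on E2, were among the 10.

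On the DDT array, fragments of other small RNAs and GC-rich miRNAs were higher than on vehicle. For more ribosomal and other small RNA relative to miRNA in the DDT sample, 6 of 6 probes for 5S RNA had a DDT over vehicle ratio above that of the median miRNA. The explanation also predicted a larger 5S excess on DDT than on BPA and E2, where the fragment list was at 0.03 and 0.04. That part failed, as 6 of 6 probes were above the median miRNA there too. The excess was 0.39 in log2 units on DDT, 0.75 on BPA and 0.55 on E2, so the test does not back this explanation. A trend with GC content across all miRNAs may explain part of the pattern, as removing the trend took the median of the fragment list from 0.53 to 0.28, at percentile 97.0 of random lists, just inside their middle 95%. miR-1246 and miR-720 stayed past 2-fold after that step. No test here separates a response to DDT from a difference between 2 RNA preparations.

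miR-15b was lower on all 3 treated arrays than on vehicle. The vehicle array itself stands apart as a possible explanation, and it differed 2-fold from all 3 others for 1 of 90 miRNAs, against at most 2 for another array. That 1 is miR-15b itself, so the count restates the pattern and tests nothing, and that explanation and a shared response to the 3 compounds cannot be told apart.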

How the results depend on the processing

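No paired analysis was possible because each treatment has 1 array, and leaving out a replicate was impossible for the same reason. The stricter filter, 5S scaling, spike scaling and removal of the GC trend were chosen after the data were seen. Counts below are of 2-fold differences, and "a and b" gives higher and lower. The cause of each shift was not tested. The median miRNA past the stricter filter on DDT, BPA and E2 against vehicle lay at -0.01, -0.08 and 0.08 in the reported setting, 0.27, -1.07 and -0.76 without normalization, 0.83, -1.02 and -0.41 with spike scaling, -0.32, -0.59 and -0.34 with 5S scaling, and -0.07, -0.24 and 0.09 with scaling to the median of miRNAs detected on all arrays. That last scaling shifts all probes of an array by 1 constant, dim ones included. Over all miRNAs detected on both arrays its medians were -0.21, 0.54 and 0.94.

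With a 1.5-fold threshold, 11 were lower for DDT against vehicle, and counts were 15 and 19 for BPA and 17 and 23 for E2 against vehicle. Between treated arrays, 21 were lower for DDT against E2, with 14 and 13 for BPA against E2 and 16 and 18 for DDT against BPA. With the GC trend removed, counts were 2 and 5 for DDT, 4 lower for BPA and 0 and 5 for E2 against vehicle, 10 and 3 for BPA against E2 and 6 lower for DDT against BPA. On DDT the median of miR-17-92 and its paralogous clusters was then 0.00 and that of the oestrogen-responsive list 0.07. With the authors' processed values, 6 were lower for DDT and 4 higher for E2 against vehicle, and DDT against BPA gave 8 and 3. With cyclic loess, 7 were lower for DDT, 5 lower for BPA and 0 higher for E2 against vehicle, with 2 and 2 for BPA against E2, 3 lower for DDT against BPA, and a correlation of the BPA and E2 responses of 0.74.

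With the first 2 of the 4 repeat spots, 6 were lower for DDT and 13 lower for BPA against vehicle, DDT against BPA gave 9 and 0, and the median of star strands on E2 was -0.02. With the last 2, BPA against vehicle gave 15 and 5, BPA against E2 10 and 3, and 12 were lower for DDT against BPA. With the median of the repeat spots, 2 were higher for BPA against E2, 0 were lower for DDT against BPA, and the star strands on E2 were at 0.00. Without background correction, 3 were higher for DDT and 4 lower for BPA against vehicle, with 0 and 5 for E2 against vehicle, 6 and 3 for DDT against E2, 2 and 1 for BPA against E2 and 0 lower for DDT against BPA. With plain subtraction of the background, 7 were lower for DDT, with 14 and 16 for BPA and 9 and 20 for E2 against vehicle, 15 lower for DDT against E2, 11 and 13 for BPA against E2 and 15 and 13 for DDT against BPA. With an offset of 16, 10 were higher for BPA and 6 higher for E2 against vehicle, 8 higher for BPA against E2, and 8 and 4 for DDT against BPA. With no detection filter, DDT against BPA gave 9 and 2, and with the stricter filter 1 was higher for BPA against E2 and 0 lower for DDT against BPA.

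Without normalization, 14 were higher for DDT, with 0 and 36 for BPA and 0 and 33 for E2 against vehicle, 40 and 0 for DDT against E2, 2 and 2 for BPA against E2 and 45 and 0 for DDT against BPA. Correlations were 0.06 for DDT and BPA, -0.06 for DDT and E2 and 0.90 for BPA and E2. On DDT the miR-17-92 clusters were at 0.02, the miR-23/27/24 clusters at 0.05, the oestrogen-responsive list at 0.06 and miR-92a at 0.02. On BPA miR-663, miR-1915 and miR-638 were at -0.16, -0.13 and -0.26. For DDT against E2, miR-92a, miR-92b, miR-181a, miR-103 and miR-99b were at 0.27, 0.64, 0.47, 0.62 and 0.84. With spike scaling, counts were 41 and 0 for DDT, 0 and 32 for BPA and 0 and 22 for E2 against vehicle, 50 and 0 for DDT against E2, 0 and 3 for BPA against E2 and 57 and 0 for DDT against BPA. Correlations were -0.06 for DDT and BPA, -0.15 for DDT and E2 and 0.88 for BPA and E2. On DDT the miR-17-92 clusters were at 0.46, the miR-23/27/24 clusters at 0.70, the miR-30 family at 0.08, the oestrogen-responsive list at 0.54 and miR-92a at 0.70. On BPA miR-663, miR-1915 and miR-638 were at -0.14, -0.11 and -0.23, and for DDT against E2 miR-92a, miR-92b, miR-181a, miR-103 and miR-99b were at 0.58, 0.94, 0.76, 0.92 and 1.14.

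With 5S scaling, 6 were lower for DDT, with 20 and 15 for BPA and 0 and 21 for E2 against vehicle, 22 and 0 for DDT against E2, 2 lower for BPA against E2 and 12 and 42 for DDT against BPA, and the BPA and E2 responses had a correlation of 0.88. With scaling to the median of miRNAs detected on all arrays, 10 were higher for DDT, 43 higher for BPA and 99 higher for E2 against vehicle, 310 were lower for DDT against E2, BPA against E2 gave 2 and 2, and DDT against BPA 15 and 48. This scaling cannot change the correlations found without normalization, 0.06 for DDT and BPA, -0.06 for DDT and E2 and 0.90 for BPA and E2. The list of miRNAs higher in luminal tumours was at 0.54 on E2.

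Of the 90 differences named by rank, 17 had the opposite sign without normalization, 19 with spike scaling, 3 with 5S scaling, 2 with scaling to the median of miRNAs detected on all arrays and 1 with cyclic loess. Against vehicle, 2 of 20 named for DDT, 4 of 20 for BPA and 2 of 20 for E2 were at least 2-fold in all settings. Between treated arrays, 5 of 10 were for DDT against E2, 4 of 10 for DDT against BPA and 0 of 10 for BPA against E2. Not all named differences had reached 2-fold in the reported setting. Across the settings, miR-1246 on DDT against vehicle was 2.30 or more, miR-720 ranged from 1.60 to 3.77, miR-21 on E2 from -4.31 to -2.42 and miR-15b on BPA from -3.36 to -1.72.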

Other observations

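The comparisons below were chosen after the values were seen. miRNAs encoded side by side did not always move together. miR-125a-5p lies beside miR-99b and let-7e within SPACA6 in assembly GRCh38.p14, and on BPA it was at -2.23 while its neighbours were at 0.40 and 0.40. On E2 the 3 were at -1.25, 0.77 and -0.01. Within MCM7, miR-106b was at -1.06 on BPA while miR-93 and miR-25 were at 0.53 and 0.35. In MIR222HG, miR-221 was at -0.31 on BPA and -0.66 on E2, while miR-222 was at 0.99 and 0.88. miR-15b and miR-16, by contrast, were both lower on all 3 treated arrays, at -1.94 and -0.70 on DDT, -2.32 and -1.57 on BPA, and -1.22 and -1.14 on E2, although miR-16 is also encoded in DLEU2 beside miR-15a, so its probe does not read the miR-15b cluster alone. Some of these signs turned with the scaling, as for miR-16 on DDT at 0.40 with spike scaling and miR-222 on E2 at -0.03 without normalization. In addition, miR-106b missed the stricter filter on BPA and miR-221 missed it on E2, so the size of those differences is uncertain. The -0.31 of miR-221 on BPA had a standard error of 0.17, so it was under 2 standard errors.

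miR-1308, one of the fragments of other small RNAs, read 3942 units above the empty spots on vehicle and 18055 on DDT, a ratio of 4.58, yet its normalized difference was 0.52 ± 0.30. Its difference on BPA against vehicle was also 0.52 ± 0.30, and DDT against BPA gave 0.00 ± 0.05. Quantile normalization sets values by rank, so a ratio of intensities need not be kept, and this also enters the medians of the fragment list. Removing the GC trend also changed which lists stood out. Before, 11 of 45 list medians lay outside the middle 95% of random lists, where 2.2 would be expected for independent lists, and after it 4 did. The lists share the vehicle array and some of their members, and related miRNAs are not independent, so 11 against 2.2 cannot be read as an excess. The 4 after removal were let-7 on DDT at 0.36 and on BPA at 0.64, the miR-15/16 family on E2 at -0.89, and star strands on BPA at 0.77. Before removal let-7 stood at percentiles 83.3 on DDT and 50.6 on BPA. let-7a, let-7c, let-7f and let-7g have a GC content of 31.8% to 40.9%, so subtracting the trend raises them. The random lists were matched on signal and not on GC content, so the let-7 result may be a product of the removal. Of the 15 star strands detected on BPA and vehicle, 1 passed the stricter filter, so most lay outside the fit of the trend.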
